A study of Danio rerio with 147 samples.

How the data were processed

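Total RNA of whole wild-type zebrafish was labelled with Cy3 and hybridised to one-colour Agilent arrays, 147 arrays on 38 slides, per the labels. Each sample pooled animals, from around 50 embryos early on to 2 fish at juvenile and adult ages sampled by sex, and the labels call the replicates biological. The groups, 71 of time point and sex, were read from the labels; the 4 samples of 1y9m are labelled as mixed and formed their own group, outside every comparison of sexes.

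The values used were the processed signal intensity of each spot, per the file headers, together with the flags for signal well above background and for outlier spots (unit "other", 0 or 1, per the file headers). The deposited table of values equalled these intensities on 147 of 147 arrays within a relative difference of 1e-06. The scanner software was Agilent Feature Extraction 10.5.1.1 per the file headers and 10.7 per the submitters' processing notes. It had already subtracted background and detrended within each array, and nothing between arrays. The median spot intensity and median local background intensity, per the file headers, served only for the normexp alternative. Mean spot intensity, scan dates, hybridisation batches and RNA extraction batches were not given in the sources used here.

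Arrays carried 45220 spots, 43803 of them no control, with 43603 distinct probes of which 50 were printed more than once. In all 1907 outlier spots were left out, and 14 were saturated. Probes were named through their RefSeq accession and the table of symbols supplied with the data, which belongs to the GRCz12tu assembly and was used for names, and for the order of genes along chromosomes in a single check. This named 15163 probes with 10536 symbols and left 28440 without a name. Of accessions starting with NM 14767 of 16036 were named, of XM 391 of 2989, of other accessions 5 of 10004, and none of 7356 Ensembl, 7036 TC and 182 XR entries. Unnamed probes were fitted apart.

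The log2 signal was scaled by subtracting the 75th percentile of all spots that were no control. A probe was kept if it was well above background on all arrays of at least 1 group: 37140 probes were kept and 6463 removed, with 148 named genes among the losses. Detection counts of a gene took any of its probes, but the bounds of calr, tpm4b and smyhc1 and the floored values took the fitted probe alone. Each gene was represented by its kept probe with the highest mean signal; 3721 genes had several kept probes. One gene was dropped because outlier spots emptied a group, which left 10387 genes, 639 of them named by an accession or clone.

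Tests used limma 3.58.1 in R 4.3.3: a mean for each of the 71 groups in 1 fit, contrasts that weight time points equally, and moderated t-tests with 76 residual and 3.05 prior degrees of freedom (prior SD 0.29 in log2). Adjustment was by Benjamini-Hochberg within a comparison. A call needed an adjusted p under 0.05 and a change of at least 2-fold. There were 11 comparisons and 49 steps between successive time points up to 45d. Tables were read with Python 3.11.15 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

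The 25 gene lists, fixed before the data were examined, were oocyte and germ plasm, first zygotic and axis, somite clock, skeletal muscle, heart, red cell, neural, lens, retina, liver, pancreas and gut, skeleton and matrix, ovary, testis, yolk and estrogen, replication and mitosis, leukocyte and antigen presentation, ageing and damage, hatching gland, pigment, stress and early response, hox, ribosomal protein, respiratory chain and ATP synthase, and proteasome. They were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Matches by older names that belong to other genes were left out by name: scxa from the somite list, rnd2 from the retina list and rps6kal from the ribosomal list. The symbol wnt11 stayed in the first zygotic and axis list, where it was matched as an alternative name of wnt11f2.

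Named genes in each comparison were the 6 largest rises and 6 largest falls among called genes with a gene symbol, ranked by fitted log2 change. List members were named to illustrate their list, up to 4 a list.

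In a self-test, 200 of 10192 genes of simulated arrays were given a change, besides a separate gene set shifted for the list test. Of 100 genes changed by 1.5 in log2, the fit recovered 83 in cleavage against egg, 96 in gastrula, 99 in segmentation, 98 in pharyngula, 95 in hatching, 99 in larva, 100 in adult against larva, 99 in female against male, 88 in that difference by age, 97 in old against young and 63 in ageing by sex. Of 100 changed by 3.00 it recovered 98, 100, 100, 100, 99, 100, 100, 100, 99, 100 and 94. Unchanged genes called were 7, 3, 0, 0, 2, 0, 0, 0, 4, 2 and 5 by limma. The simulation drew independent noise with 1 SD per gene around a flat mean. It held no slide effect, no background floor and no genes that differ between replicate fish. These counts therefore check the fit and say little of false calls on the real arrays.

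Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the array median, scaling to 10 spike-in probes of 32 spots each, and the 75th percentile over the 13717 probes detected on all arrays. Further ones were no filter, a filter asking for detection on 0.5 of the arrays, the mean of all kept probes, the deposited table of values, and array weights (0.0377 to 4.66, 13 under 0.5). Slide entered as a random block (correlation 0.312) and as a fixed block where estimable (rank 105 of groups and slides), and replicate number as a block. Others were group means as units, a threshold of 1.5-fold, the adjusted p alone, each array left out, the 1y9m samples left out, and these together with 65d male sample 2. Scaling on probes detected on all arrays, the fixed block, the fits without the 1y9m and 65d samples, the floored values the regrouping of old against young within each sex and the regrouping of sexes by age without 65d male sample 2 were added after the data were examined.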

Results

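RNA was measured with one-colour arrays in zebrafish from the unfertilised egg to fish of 1y9m, on 147 arrays in 71 groups of time point and sex. The labels describe the replicates as biological. Of the groups, 67 had 2 arrays, 3 had 3 arrays and 1 had 4 arrays, so the number of arrays limited the precision of every value below. Sexes were sampled apart at 10 ages from 55d to 1y6m, and the 1y9m samples were labelled as mixed. Adjusted p-values came from limma with Benjamini-Hochberg adjustment, and they measure only the spread between replicates of these samples. That spread is 1 value per gene, pooled over all 71 groups, and not that of the arrays compared alone. Replicate pairs differed in it, with an SD of log2 differences of 0.352 in larvae of 8d and 1.42 in males of 65d. A p-value can thus be too strict where replicates were alike and too lax where they were not. A gene was called changed at an adjusted p under 0.05 and a change of at least 2-fold. In all, 10387 named genes were tested in 1 fit. Changes are log2 differences of group means with a standard error (SE), after scaling each array to its 75th percentile. Where no array of an arm read a gene well above background, the change is given as at least N-fold. That bound is the mean of the detected arm minus the mean of a floor in the other arm. The floor of a group is the larger of its fitted signal and the lowest signal well above background on its arrays. Where an arm read a gene on only some arrays, low signals inflate the change; where raising both arms to the floor moved it by more than 2-fold, that value follows as floored, except where a difference was compared by age or sex. Gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation. List medians are given relative to the median of all genes in the same comparison unless called fitted, because 4 other scalings shifted that median. These were quantile normalization, the array median, the spike-in controls, and the 75th percentile of the probes detected on all arrays.

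Which transcripts changed between successive time points, from the egg to 45d? Of 49 steps, the single step from egg to zygote had by far the most called genes, 5169. The step medians were 15 genes in 3 cleavage steps, 241 in 5 blastula steps and 749 in 6 gastrula steps. In 15 segmentation steps the median fell to 16 genes, and in 6 pharyngula steps to 9.50. Hatching steps had a median of 112 (3 steps) and larval steps 436 (9 steps, range 2 to 1135), and the juvenile step had 261. At the step from 11h40min to 12h, 0 genes were called by limma with Benjamini-Hochberg adjustment, where 126 had an unadjusted p under 0.05. Spike-in scaling gave 3029 genes at the zygote step, 200 per gastrula step and 3 per segmentation step. In 25 of the steps the time points shared 2 slides, and among those the medians were 705 in gastrula, 14 in segmentation and 12 in pharyngula. The plot of called genes per step shows the sequence. With background subtraction by normexp, 1514 genes were called at the zygote step and 2.5 per gastrula step. Slide as a random block raised the medians to 43 in cleavage, 31 in segmentation, 21.5 in pharyngula and 203 in hatching. The other periods stayed within 1.5 times.

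**Figure D1:**
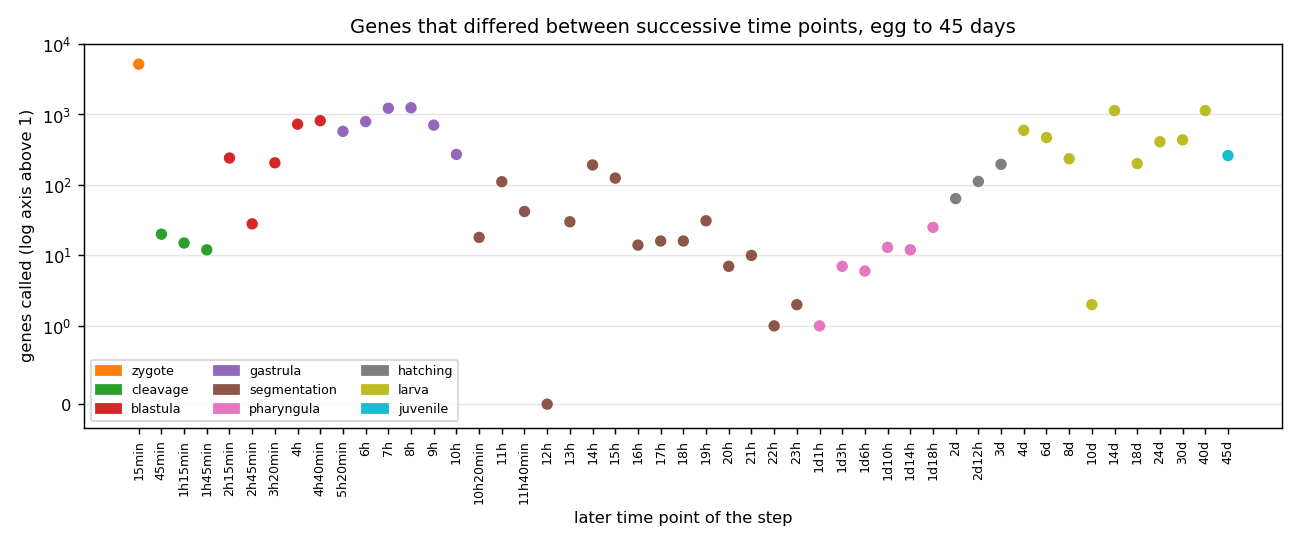
Genes called changed between successive time points from the egg to 45d (y, number of genes, log axis above 1) against the later time point (x), 1 point per step, coloured by its period. The zygote step stands at 5169 and the gastrula median at 749, against 16 in segmentation.

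Which transcripts differed between the cleavage embryo and the unfertilised egg, before transcription of the embryo starts? In cleavage (7 arrays against 2), 1994 genes were higher and 3991 lower than in the egg. Of the lower genes 1057 were well above background on no cleavage array. The egg arrays were dim, with a 75th percentile of 125 and 186, against 412 to 780 in cleavage. Undetected genes thus sat higher in the egg after scaling, as coro2aa at -6.56 there against ctsba at -7.88 in cleavage. This alone can give a fall, and without the filter on dim probes 4077 genes were lower and 1994 higher. The adaptor gene stap2b rose at least 556-fold, with other probes at 3.64 and 8.98. The coronin coro2aa rose at least 152-fold and the ribonucleotide reductase subunit rrm2b at least 145-fold. Also higher were calr, for a calcium-binding chaperone, at least 235-fold, although another calr probe read -0.62, and ms4a17a.9 (at least 56.3-fold) and txlnbb (at least 47.1-fold). The lysosomal protease gene ctsba was detected on both egg arrays and on none of the 7 cleavage arrays, a fall of at least 35151-fold with a wide error (SE 2.69, adjusted p = 3.70e-08). Yet ctsba also read 5.73 and -8.16 on replicate arrays of 3m15d females, and 5.61 and -8.37 on those of 7m males, so it differed between fish of one age and sex. The tropomyosin gene tpm4b fell at least 1210-fold, where another of its probes read 0.07. The transporter abcc2 fell at least 274-fold and mlpha at least 204-fold; slc5a5 (-10.71, SE 0.76, floored -9.56; another probe -7.18) and rangap1b (-7.72, SE 0.67, floored -6.16) fell too, each detected on 1 cleavage array.

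Among the lists, 33 of 71 genes of the respiratory chain and ATP synthase rose and 14 fell, with a fitted median of 0.43, where all genes had -0.67. Of these atp5f1b changed by 4.23 and atp5if1a by 3.57, against ndufb6 at -2.46. That list passed camera at an adjusted p of 1.18e-05 but not otherwise (adjusted p = 0.948 with an estimated correlation). The proteasome list had 21 of 40 higher and 5 lower, with a median 1.75 above all genes (adjusted p = 3.95e-06; adjusted p = 0.948 with an estimated correlation), with psmc1a at 4.30 and psmd11b at -2.85. No other list passed. Of 19 oocyte and germ plasm genes none rose and 8 fell, among them eomesa (-2.59) and cpeb1b (-2.29), at an adjusted p of 0.757. Fallen members of lists that did not pass included col1a1a (-5.48) among 13 of 28 matrix genes, 22 pancreas and gut genes, 25 hox genes and 28 ribosomal protein genes. Those lists had adjusted p-values of 0.233, 0.233, 0.381 and 0.233. Members undetected in both arms may be among these falls, since undetected genes sat higher on the dim egg arrays. Of called genes 33.3% were higher here, against 58.1% with quantile normalization, 45.0% with median scaling, 88.5% with spike-in scaling and 61.0% when scaled on probes detected everywhere. The median of all genes was -0.67 and lay between -0.37 and 0.63 under the other scalings. No slide held both arms. Slide as a fixed block, joined through a single cleavage array on a slide with adults, gave 1979 higher and 3801 lower. Spike-in scaling gave 3999 higher and 520 lower, normexp 923 and 2043.

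Which transcripts appeared or were lost across the blastula period, between cleavage and gastrula? In the gastrula (13 arrays against 7), 2847 genes were higher and 2990 lower. The ventral repressor vox rose at least 7610-fold (another probe 12.41), the cathepsin gene ctsll at least 7579-fold and ctsba, which differed between replicate adults, at least 7093-fold (SE 1.59). The keratin krt18a.1 rose at least 6545-fold, sult6b1 at least 5595-fold and the adhesion molecule alcamb at least 5316-fold (another probe 11.22); all of these were detected on 13 gastrula arrays and no cleavage array. Single genes that fell included mos (-6.40, SE 0.37), which acts in oocyte maturation, and btg4 (-6.35, SE 0.71), which acts in maternal RNA decay. Also lower were alg13 (-6.64, SE 0.36), rasef2 (-6.46, SE 0.39), gata2b (-6.37, SE 0.26, floored -5.28) and ndel1a (-6.24, SE 0.20).

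Of 37 first zygotic, axis and germ layer genes 34 rose and none fell, with a median 7.68 above all genes (adjusted p = 3.48e-16, and 9.18e-05 with an estimated correlation). They included tbx16 (at least 4195-fold), aplnrb (12.55, floored 11.12), mixl1 (3.33) and wnt11 (1.38), the last matched as an alternative name of wnt11f2. The somite list had 18 of 22 higher and none lower (adjusted p = 7.32e-06, and 0.000822 with an estimated correlation), with foxc1a at least 707-fold and nrarpa at 10.16. Its fitted median was 4.32, and 3.47 with undetected genes at their bound. Ribosomal protein genes rose in 71 of 73 cases, among them rpl31 (3.19) and rps6 (2.79), at an adjusted p of 6.06e-14 (adjusted p = 0.449 with an estimated correlation). Neural genes had 19 of 32 higher and 1 lower at 0.000351 (adjusted p = 0.263 with an estimated correlation), sox2 at 8.58 and plp1a at -2.41. Of 36 hox genes 24 rose and 4 fell, hoxc6a at least 89.8-fold and hoxc11a by -2.62, at 0.00355 (adjusted p = 0.449 with an estimated correlation). Oocyte and germ plasm genes fell in 15 of 19 cases, dazl by 5.21 and cth1 by 4.54, while pou5f3 rose by 1.08; the list passed at 0.0161 (adjusted p = 0.59 with an estimated correlation). Hatching gland genes had 5 of 6 higher, klf17 at 8.15, at 0.0359 (adjusted p = 0.158 with an estimated correlation). Liver (13 higher, 2 lower, adjusted p = 0.00355) and proteasome (13 higher, adjusted p = 0.00355) passed only at the preset (adjusted p = 0.449 and adjusted p = 0.548 with an estimated correlation). In all 11 of 25 lists passed, 2 of them also with an estimated correlation. Split by direction, 48.8% of called genes were higher, 23.7% with median scaling, 38.04% with spike-in scaling and 52.2% on probes detected everywhere. The median of all genes, 0.07, lay between -1.02 and 0.17 under the other scalings. No slide held both arms. Of 100 regroupings of these arrays the highest had 4177 called genes, against 5789 for the real grouping in the same 2-group fit.

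Which transcripts changed when the body axis segments? In segmentation (31 arrays against 13 of gastrula), 2196 genes were higher and 2247 lower. Contractile genes rose: myl13 by 9.83 (SE 0.15), tnnc2.2 at least 225-fold, smyhc1 at least 204-fold (another probe 5.17), and the muscle regulator myog at least 122-fold. The hatching enzyme gene he1.1 rose by 9.82 (SE 0.26, floored 8.35) and the matrix gene ccn2a by 9.69 (SE 0.13, floored 8.08), though another ccn2a probe gave 4.17. Early genes fell: the endoderm factor sox32 (-8.72, SE 0.24), pou5f3 (-6.51, SE 0.35), ccna1 (-6.66, SE 0.33) and wee2 (-6.50, SE 0.20; another probe -5.01). Lower too were nnr (-8.25, SE 0.22) and fhdc3 (-6.62, SE 0.20, floored -5.56), with -2.94 at another fhdc3 probe.

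Skeletal muscle genes rose in 26 of 29 cases, with a median 4.71 above all genes (adjusted p = 1.20e-14, and 0.00913 with an estimated correlation); acta1a rose at least 95.6-fold and mylpfb by 2.16. Of 36 hox genes 34 rose (adjusted p = 1.61e-17, and 0.00112 with an estimated correlation), hoxa10b by 7.48 (floored 6.16) and hoxa2b by 7.31 (floored 5.98). Neural genes rose in 25 of 32 cases (adjusted p = 3.60e-09, and 0.0127 with an estimated correlation), with gfap at 8.54 and neurod1 at least 99.4-fold. Red cell genes had 11 of 18 higher and 1 lower (adjusted p = 2.58e-05, and 0.0339 with an estimated correlation): the embryonic globin hbbe3 changed by 8.46 and hbae3 by 7.43, the other globin hbaa2 by -1.18. First zygotic and axis genes fell in 30 of 37 cases (adjusted p = 3.60e-09, and 0.00656 with an estimated correlation), dharma by 6.25 (floored -4.22) and ndr1 by 6.14, whereas wnt11 rose by 5.74. As wnt11 was matched as an alternative name of wnt11f2, its rise may not be that of the gene meant. Heart genes had 11 of 14 higher, hand2 at 5.09 and myl7 at 4.43, and gata6 at -3.06 (adjusted p = 0.000506; adjusted p = 0.0517 with an estimated correlation). Oocyte and germ plasm genes fell in 18 of 19 cases, nanog by 6.20 and h1m by 5.95 (adjusted p = 0.000149; adjusted p = 0.426 with an estimated correlation). Pigment genes had 9 higher and 1 lower, sox10 at 5.31 and pnp4a at -5.29 (adjusted p = 0.008; adjusted p = 0.132 with an estimated correlation). The somite list was mixed, 7 higher and 3 lower, with meox1 at 6.60 and her7 at -1.99 (adjusted p = 0.272). In all 17 lists passed, 5 of them also with an estimated correlation. Of called genes 49.4% were higher, against 38.3% with median scaling, 78.9% with spike-in scaling and 66.7% on probes detected everywhere; the median of all genes was -0.19 and ranged from -0.44 to 0.51. Inside the 2 slides that held both arms, 86.0% and 96.9% of the called genes had the same direction; the muscle median there was 0.54 and 6.34, and with slide as a random block 2209 were higher and 2246 lower. Normexp left 1143 higher and 1091 lower. In the regroupings 0 genes were called at most by limma, against 4401.

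Which transcripts set the pharyngula apart, the period said to be the most alike across vertebrates? In the pharyngula (12 arrays against 31 of segmentation), 1663 genes were higher and 1040 lower. Muscle and lens genes led the rises: the calcium buffers pvalb4 by 9.92 (SE 0.17, floored 8.77) and pvalb1 by 8.92 (SE 0.17), and the crystallins crygmxl2 by 9.37 (SE 0.26, floored 8.12), crygm2d18 by 9.35 (SE 0.29) and cryba1b by 9.29 (SE 0.18). The carrier slc25a4 rose by 8.76 (SE 0.15). Somite genes led the falls: mespba (-6.66, SE 0.27, floored -5.64), her7 (-6.50, SE 0.28), tbx6 (-5.61, SE 0.20) and tbx16 (-5.59, SE 0.18; another probe -4.04). Posterior regulators fell as well, wnt8a (-5.85, SE 0.37, floored -4.44) and cdx1a (-5.85, SE 0.14), although another cdx1a probe gave -0.37.

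Skeletal muscle genes rose in 24 of 29 cases, 4.82 above all genes, with casq1b at 8.37 and tnnt3a at 7.96, and 1 fell (adjusted p = 1.15e-18, and 0.00278 with an estimated correlation). Pigment genes rose in 12 of 18 cases (adjusted p = 5.07e-08, and 0.00278 with an estimated correlation), tyrp1b by 8.42 and gch2 by 6.17. Red cell genes had 11 higher and none lower (adjusted p = 1.05e-07, and 0.00448 with an estimated correlation), with slc4a1a at 4.67. Lens genes had 16 of 25 higher, crybb1 at 7.55, and 1 lower, crygs4 at -1.41 (adjusted p = 7.82e-09, and 0.0226 with an estimated correlation). Neural genes had 19 of 32 higher (adjusted p = 8.83e-08, and 0.0208 with an estimated correlation), gad1b at 4.69 and snap25a at 4.17. First zygotic and axis genes fell in 25 of 37 cases (adjusted p = 1.45e-08, and 0.00448 with an estimated correlation), cdx4 at -5.44. The somite list had 12 of 22 lower, mespaa at -5.34 (adjusted p = 0.000139, and 0.00448 with an estimated correlation). Leukocyte genes had 8 higher and 3 lower, mpx at 5.69 (adjusted p = 0.0319; adjusted p = 0.376 with an estimated correlation). Proteasome genes passed camera at 0.0122 with 0 members called either way by limma (adjusted p = 0.663 with an estimated correlation). Of 16 lists that passed, 7 did so with an estimated correlation. The share of called genes that were higher was 61.5%, against 45.2% with median scaling, 84.8% with spike-in scaling and 81.9% on probes detected everywhere. The median of all genes was -0.15 and ranged from -0.36 to 0.25. On the 2 shared slides 84.6% and 90.2% of called genes had the same direction, and with slide as a fixed block 868 were higher and 357 lower. Normexp gave 808 and 494, and the highest regrouping had 141 called genes against 2641.

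Which transcripts changed at hatching? In hatching embryos (6 arrays against 12 of pharyngula), 962 genes were higher and 416 lower. The largest fitted rises were those of the collagen gene col10a1a (7.19, SE 0.29, floored 5.73), the muscle enzyme gene ampd1 (6.72, SE 0.18), lgsn (5.83, SE 0.21) and foxq2 (5.53, SE 0.36, floored 4.01). The cartilage gene matn1 rose at least 12.8-fold and six7 by 5.37 (SE 0.31; another probe 2.06). The Nodal inhibitors lft1 and lft2 fell by 3.92 (SE 0.37) and 3.25 (SE 0.35), and cdx4 fell by 3.29 (SE 0.26). Also lower were wfikkn1 (-4.44, SE 0.36), ctsll (-3.19, SE 0.22) and tgm1l4 (-3.17, SE 0.19).

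Retinal genes rose in 20 of 31 cases, 1.98 above all genes (adjusted p = 3.75e-17, and 0.000258 with an estimated correlation): rom1b by 4.47, opn1mw1 by 4.36 and crx by 4.24. Lens genes rose in 17 of 25 cases (adjusted p = 4.46e-12, and 0.0182 with an estimated correlation), crygm5 by 4.31 (floored 2.66). Replication and mitosis genes fell in 17 of 36 cases, gmnn by 1.84 and mcm3 by 1.29 (adjusted p = 7.95e-11; adjusted p = 0.268 with an estimated correlation). Liver genes had 7 higher, fabp10a at 2.89 (adjusted p = 0.000172; adjusted p = 0.268 with an estimated correlation), and pancreas and gut genes 8 higher and 2 lower, ctrb.1 at least 2.74-fold up (adjusted p = 0.00484; adjusted p = 0.458 with an estimated correlation). First zygotic and axis genes had 1 higher and 15 lower (adjusted p = 0.000606; adjusted p = 0.205 with an estimated correlation). The hatching enzymes he1.1 (-2.71) and he1.2 (-2.89) fell, but their list did not pass (3 lower, adjusted p = 0.101). The ovary list had 2 higher and 6 lower, or 2 and 3 adjusted over the list alone. Of 9 lists that passed, 2 did so with an estimated correlation. Of called genes 69.8% were higher, against 53.3% with median scaling, 89.9% with spike-in scaling and 87.8% on probes detected everywhere, and the median of all genes was -0.11, ranging from -0.27 to 0.15. On the single shared slide 91.2% of called genes had the same direction, with list medians of 0.56 for retina, 0.31 for lens and -0.49 for proliferation; slide as a fixed block left 484 higher and 195 lower. Normexp gave 406 and 191, and the highest regrouping had 0 called genes by limma against 1376.

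Which transcripts changed between hatching embryos and larvae? In larvae of 4d to 40d (18 arrays against 6 of hatching), 1444 genes were higher and 1251 lower. Digestive protease genes led: c6ast4 rose at least 2290-fold, ela3l by 12.70 (SE 0.25; other probes 10.03 and 12.60), ctrl by 12.01 (SE 0.28), ctrb.2 by 11.80 (SE 0.33), ctrb.3 by 11.73 (SE 0.32) and ctrb.1 by 11.68 (SE 0.32). The hatching enzymes he1.1 (-9.30, SE 0.36, floored -8.03) and he1.2 (-8.37, SE 0.33, floored -6.70) fell, read on 3 and 2 of the 18 larval arrays. The embryonic globins hbbe3 and hbae3 fell by 7.32 (SE 0.29) and 4.29 (SE 0.30). The ear gene oc90 fell by 4.25 (SE 0.24; other probes -2.20 and -1.20) and cmn by 4.19 (SE 0.22).

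Pancreas and gut genes rose in 24 of 30 cases (adjusted p = 9.54e-26, and 0.000355 with an estimated correlation), cpa1 at least 612-fold and ins by 1.16, while ptf1a, which acts in the forming pancreas, fell by 1.42. Leukocyte and antigen presentation genes rose in 26 of 29 cases (adjusted p = 5.61e-11, and 0.00225 with an estimated correlation): psmb13a by 6.64, cd74b by 6.08 and mpx by 1.09. Liver genes had 13 of 23 higher (adjusted p = 2.65e-12, and 0.0102 with an estimated correlation), ahsg2 at least 424-fold and fabp10a by 7.93. Retinal genes had 22 higher and 4 lower (adjusted p = 4.67e-10, and 0.00697 with an estimated correlation), opn1mw1 at 6.21 and vsx1 at -1.73. Pigment genes fell in 11 of 18 cases (adjusted p = 9.02e-05, and 0.0218 with an estimated correlation), gch2 by 3.42 and mitfa by 2.75. Hox genes fell in 25 of 36 cases (adjusted p = 4.97e-07, and 0.0495 with an estimated correlation). Replication and mitosis genes had 1 higher and 32 lower, kif11 at -2.41 (adjusted p = 5.61e-11; adjusted p = 0.229 with an estimated correlation). Neural genes had 1 higher, mpz at 1.54, and 20 lower, neurog1 at -3.66 (adjusted p = 1.68e-05; adjusted p = 0.0764 with an estimated correlation). Ageing and damage genes had 10 higher and none lower (adjusted p = 0.0277; adjusted p = 0.229 with an estimated correlation), and stress genes 7 higher and 1 lower (adjusted p = 0.0277; adjusted p = 0.243 with an estimated correlation). Of 14 lists that passed, 6 did so with an estimated correlation. Of called genes 53.6% were higher, against 45.05% with median scaling, 70.4% with spike-in scaling and 70.8% on probes detected everywhere, and the median of all genes was -0.16, between -0.28 and 0.12 under other scalings. On the 2 shared slides 93.4% and 95.6% of called genes had the same direction, and the pancreas and gut median there was 5.91 and 8.01. The first of these slides held a larval array of 4d alone, so much of that rise was present by 4d. Slide as a fixed block left 1242 higher and 1142 lower. Normexp gave 901 higher and 657 lower, and the highest regrouping had 193 called genes against 2510.

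**Figure D2:**
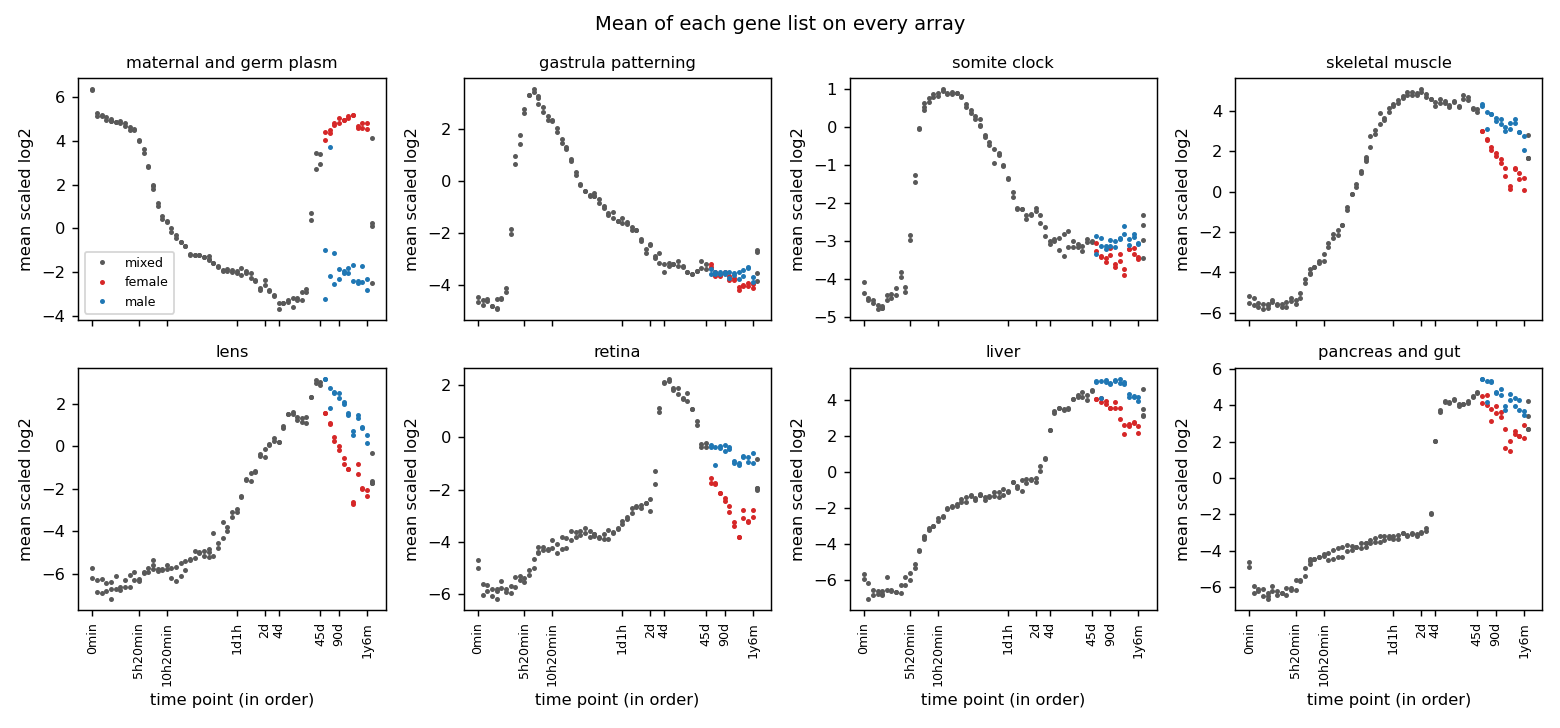
Mean of the genes of 8 lists on every array (y, log2 signal scaled to the array's 75th percentile) along the time points in order (x), 1 point per array, grey for mixed, red for female and blue for male samples. Between hatching and larvae the median pancreas and gut gene rose by 8.48 and between segmentation and pharyngula the median muscle gene by 4.66.

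Which transcripts set adults apart from larvae? In adults of 90d to 1y6m (28 arrays against 18), 2119 genes were higher and 2136 lower. Yolk precursor genes rose, vtg5 by 9.15 (SE 0.40) and vtg4 by 6.20 (SE 0.45), with females and males weighted equally. Higher too were fhdc3 by 7.77 (SE 0.19; another probe 4.42), kop by 6.19 (SE 0.22, floored 5.00), styxl1 by 6.14 (SE 0.13) and the SUMO ligase gene pias4b by 5.91 (SE 0.13). Crystallins of the lens were among the largest falls: crygm2d18 (-14.70, SE 0.26, floored -13.18), read on 5 of 28 adult arrays, crygmxl2 (-10.46, SE 0.23), read on 15, crygm2d13 (at least 179-fold), crygm2f (-8.96, SE 0.18) and cryba1b (-8.49, SE 0.16). The embryonic globin hbae1.1 fell by 9.23 (SE 0.14).

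Neural genes fell in 28 of 32 cases (adjusted p = 8.90e-14, and 0.0017 with an estimated correlation), elavl3 by 4.63 and pax6a by 3.95, while the myelin gene plp1a rose by 1.46. Retinal genes fell in 28 cases and rose in 2 (adjusted p = 9.24e-13, and 0.0017 with an estimated correlation): the opsins moved apart, opn1mw1 at -7.93 and opn1mw4 at 5.24 (floored 4.11). Hox genes fell in 34 of 36 cases (adjusted p = 1.97e-11, and 0.00856 with an estimated correlation). Skeletal muscle genes fell in 21 of 29 cases (adjusted p = 9.59e-10, and 0.0478 with an estimated correlation), mylpfb by 7.74 and smyhc1 by 6.29. Pigment genes had 1 higher and 12 lower, gch2 at -4.85 (adjusted p = 0.00035, and 0.0478 with an estimated correlation). Oocyte and germ plasm genes rose in 18 of 19 cases, dazl by 5.82 (adjusted p = 3.42e-05; adjusted p = 0.329 with an estimated correlation). Changes in this comparison average females and males, which differed. Over all ages sampled by sex, the mean of this list was 4.066 to 5.202 in females, above every larval array (highest 3.434). In males it was -3.246 to -0.9788, within the larval range from -3.684, with a male array near the females left out. The muscle mean was 1.449 in females and 3.394 in males, the neural mean -2.338 and -0.6. Testis genes had 23 of 31 higher, spo11 at 5.45 and sycp3 at 4.41, with a fitted median of 2.44, or 1.64 with undetected genes at their bound (adjusted p = 3.62e-05; adjusted p = 0.283 with an estimated correlation). Yolk and estrogen genes had 6 of 7 higher (adjusted p = 0.00585; adjusted p = 0.22 with an estimated correlation). Lens genes had 9 higher, crygs1 at 5.75 and crygm6 at 5.14, and 16 lower, lim2.4 at -7.12 (adjusted p = 0.0141; adjusted p = 0.356 with an estimated correlation). Red cell genes did not pass, with hbaa2 at 4.82 and hbbe2 at -7.80 (adjusted p = 0.132). Leukocyte genes had 13 higher, or 12 adjusted over the list alone, and 2 lower (adjusted p = 0.044; adjusted p = 0.356 with an estimated correlation). Of 19 lists that passed, 5 did so with an estimated correlation. Of called genes 49.8% were higher, against 62.2% with median scaling, 72.5% with spike-in scaling and 35.1% on probes detected everywhere. The median of all genes was 0.12 and ranged from -0.19 to 0.63. No slide held both arms; the highest regrouping had 2684 called genes against 4171.

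Which transcripts differed between females and males? Over the 10 ages from 55d to 1y6m (20 arrays against 20), 2905 genes were higher in females and 3631 lower. Egg coat genes were among the most female: zp3a.1 by 12.72 (SE 0.53, floored 11.16), zp2.5 by 12.32 (SE 0.57), zp2.1 by 12.11 (SE 0.55) and zp2l1 by 11.52 (SE 0.50). The oocyte linker histone h1m was higher by 12.18 (SE 0.53) and the yolk precursor vtg4 by 12.09 (SE 0.47). Male-biased genes included the tubulin tuba7l (-7.89, SE 0.22), the bile acid enzyme gene cyp8b1.3 (-7.30, SE 0.29) and sult2st3 (-6.70, SE 0.23). The meiotic cohesin gene rec8b was detected on all 20 male arrays and on no female array, at least 31.3-fold lower in females; ccdc83 (-6.18, SE 0.21) and rab36 (-6.15, SE 0.24) were also lower.

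Ovary genes had 27 of 31 higher and 1 lower (adjusted p = 8.32e-08; adjusted p = 0.227 with an estimated correlation). Oocyte and germ plasm genes, which share members such as btg4 with the ovary list, had 17 of 19 higher, ca15b at 11.05 and btg4 at 10.89 (adjusted p = 2.87e-06; adjusted p = 0.227 with an estimated correlation). Testis genes had 22 of 31 lower, rsph9 at -5.85 (floored -4.40) and tekt1 at -5.42 (adjusted p = 0.00153; adjusted p = 0.319 with an estimated correlation). Against that list's name, ccna1 was higher in females by 7.83 and the steroid enzyme gene cyp17a1 by 3.07. Yolk and estrogen genes had 5 of 7 higher, vtg2 at 8.37 (floored 6.84) and the estrogen receptor esr1 at 2.38, and cyp19a1b at -2.27, but did not pass (adjusted p = 0.106). Replication and mitosis genes had 32 of 36 higher, ccnb2 at 5.88, and 4 lower, mcm6 at -2.88 (adjusted p = 4.37e-07; adjusted p = 0.256 with an estimated correlation). Body tissue lists were lower in females: muscle (25 of 29, adjusted p = 3.03e-06), neural (27 of 32, adjusted p = 2.87e-06), lens (25 of 25, adjusted p = 4.37e-06), retina (27 of 31, adjusted p = 4.61e-06) and leukocyte genes (27 of 29, adjusted p = 0.000104). Each of these had an adjusted p = 0.146 with an estimated correlation. Liver genes had 19 of 23 lower and pancreas and gut genes 22 of 30 (adjusted p = 0.000464 each; adjusted p = 0.227 with an estimated correlation), and respiratory chain genes 32 of 71 (adjusted p = 1.65e-08; adjusted p = 0.277 with an estimated correlation). Of 25 lists 18 passed and 0 did with an estimated correlation, which camera computes from the spread within groups. Of called genes 44.5% were higher in females, against 58.7% with median scaling, 90.1% with spike-in scaling and 28.01% on probes detected everywhere. The median of all genes was -0.19 and ranged from -0.81 to 1.22, which makes the direction of lists with small changes relative. The labels state that eggs were pressed out of adult females before freezing. No slide held a female and a male array, though each sex lay on several slides, and with slide as a random block 2885 genes were higher and 3663 lower. The highest regrouping had 2045 called genes against 6486.

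Did the difference between the sexes change with age? In adults of 90d to 1y6m (28 arrays) against fish of 55d to 80d (12 arrays), the female minus male difference was more positive for 819 genes and more negative for 1323; for genes higher in males, a more negative value means a wider gap. Of egg coat genes, higher in females, the gap widened: zp3a.1 by 4.65 (SE 1.15, adjusted p = 0.000523), zp3a.2 by 4.40 (SE 1.04), zp2.5 by 3.98 (SE 1.24, adjusted p = 0.00499) and zp2l1 by 3.96 (SE 1.09). Also more positive were slc25a10b by 4.76 (SE 1.13; another probe 1.19) and qdprb.4 by 3.88 (SE 1.02). The heart regulator nkx2.7 moved towards males by -3.47 (SE 0.33), ankrd31 by -3.06 (SE 0.48), nt5e by -3.04 (SE 0.48), xkr9 by -2.98 (SE 0.68) and pimr110 by -2.79 (SE 0.53). The immunoproteasome subunit psmb8a moved by -4.31 with a wide error (SE 1.58, adjusted p = 0.0163). Yet psmb8a read -7.85 and 1.71 on replicate arrays of 80d males, and -0.16 and -8.88 on those of 90d females. It thus differed between fish of one age and sex.

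Ovary genes had 21 of 31 more positive and 1 more negative (adjusted p = 0.00772; adjusted p = 0.647 with an estimated correlation), and testis genes 12 more negative and 1 more positive (adjusted p = 0.00174; adjusted p = 0.375 with an estimated correlation). Muscle genes had 19 more negative (adjusted p = 5.47e-07; adjusted p = 0.117 with an estimated correlation), and retinal genes also 19, or 20 adjusted over the list alone (adjusted p = 1.26e-06; adjusted p = 0.0736 with an estimated correlation). Neural genes had 15 more negative and 2 more positive (adjusted p = 2.72e-07; adjusted p = 0.0736 with an estimated correlation), and heart genes 9 more negative (adjusted p = 0.000298; adjusted p = 0.0736 with an estimated correlation). Stress genes did not pass, with 6 more positive, fosab at 2.76 among them, and 2 more negative (adjusted p = 0.95). In all 16 lists passed and 0 with an estimated correlation in camera. These counts depended in part on 65d male sample 2, which lay at 0.775 between the male mean (0) and the female mean (1) over 336 sex-biased genes. Other males lay between -0.07 and 0.09 on that scale and females between 0.87 and 1.09. That sample correlated at 0.975 with 65d females and at 0.899 with 55d and 80d males. Without it and the 1y9m samples 530 genes were more positive and 816 more negative, and without the other 65d male 1300 and 1809. Split by direction, 38.2% of called genes were more positive, against 87.2% with median scaling, 95.2% with spike-in scaling and 9.00% on probes detected everywhere, so the direction of the shift as a whole turned with the scaling. The median of all genes was 0.10 and ranged from -0.30 to 0.55; normexp left 194 more positive and 15 more negative.

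**Figure D3:**
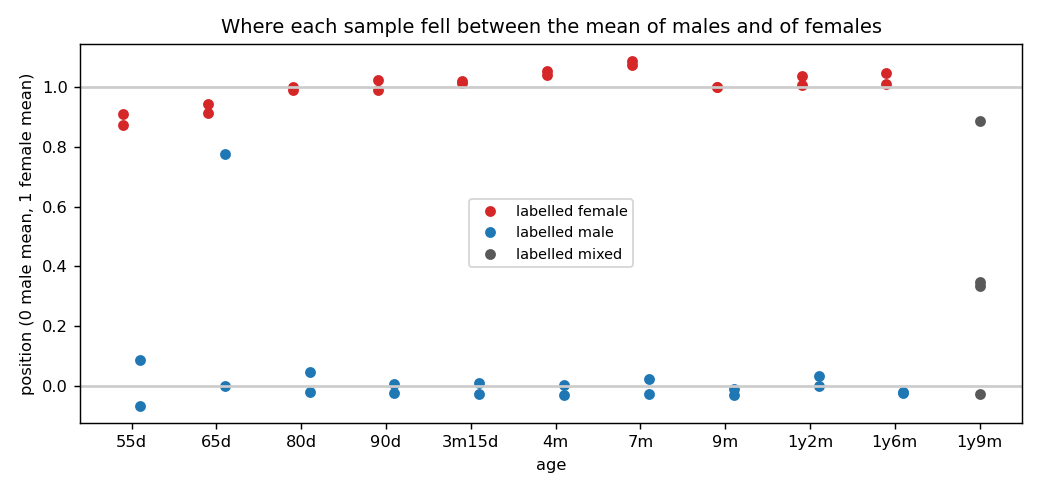
Position of each sample between the male mean (0) and the female mean (1) over 336 genes (y) against age from 55d to 1y9m (x), 1 point per array, coloured by labelled sex. The 65d male sample 2 lay at 0.775 and the mixed 1y9m samples at 0.348, 0.334, 0.887 and -0.03.

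Which transcripts changed between young and old adults? At 1y2m and 1y6m (8 arrays) against 90d, 3m15d and 4m (12 arrays), 350 genes were higher and 715 lower. The class II genes mhc2dgb and mhc2dhb rose at least 160-fold and at least 124-fold, each detected on 0 of the 12 young arrays by the scanner flag. The proteasome genes psmb12, psmb9a and psmb13a fell by 7.43 (SE 0.95), 7.13 (SE 0.87) and 6.52 (SE 0.95), each detected on 12 young and 3 old arrays (floored -6.35, -6.05 and -5.43). Neither change held in the 4 mixed samples of 1y9m, the oldest: there mhc2dgb and mhc2dhb were read on 0 arrays by the scanner flag and psmb9a, psmb12 and psmb13a on 3. At 9m mhc2dhb was read on 4 arrays, mhc2dgb on 3 and each of psmb9a, psmb12 and psmb13a on 1. Higher too were rangap1b by 6.40 (SE 0.38, floored 5.09), spag1b by 5.94 (SE 0.69, floored 4.65), cyp2aa7 by 5.30 (SE 0.58, floored 4.24) and trim35-24 by 4.34 (SE 0.45). The glucuronosyltransferase gene ugt2a2, read on 2 of 8 old arrays, fell by 8.59 (SE 0.27, floored -6.99), the crystallin crygmxl2 at least 75.4-fold and sat2a.2 at least 17.8-fold. Of 14 adult pairs of one age and sex, replicates lay over 16-fold apart in 5 for spag1b and in 3 each for cyp2aa7 and sat2a.2. They did so in 2 for mhc2dgb, in 1 for trim35-24, and in 0 for mhc2dhb, rangap1b, ugt2a2 and crygmxl2. At 1y9m cyp2aa7 was read on 0 arrays by the scanner flag, ugt2a2, spag1b and trim35-24 on 4, and rangap1b on 2.

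Lens genes fell in 17 of 25 cases, with a median 1.35 below all genes (adjusted p = 2.19e-11, and 0.0239 with an estimated correlation): crygm4 by 3.42, crygm7 by 3.19 and cryba1b by 2.66. Cartilage, bone and matrix genes fell in 13 of 28 cases (adjusted p = 4.92e-09, and 0.0239 with an estimated correlation), col1a1b by 2.81 and col10a1a by 2.66. Muscle genes had 11 lower, casq1a at -2.99 (adjusted p = 9.13e-07; adjusted p = 0.184 with an estimated correlation), and liver genes 8 lower, apoa1a at -1.71 among them (adjusted p = 9.13e-07; adjusted p = 0.182 with an estimated correlation). Leukocyte genes had 8 higher, among them hamp (2.76), tnfa (2.69) and csf1ra (2.31), and 5 lower, rag1 at -2.47, floored -1.42 (adjusted p = 0.0103; adjusted p = 0.345 with an estimated correlation). The proteasome list passed upwards although only psma5 (1.87) rose and 4 members fell, psmb8a at -3.59 on 4 old and 10 young arrays. Its fitted median was 0.40 and its fitted mean -0.23 (adjusted p = 5.05e-06; adjusted p = 0.345 with an estimated correlation). Ageing and damage genes did not pass (adjusted p = 0.554), with il1b at 1.72, mmp9 at 1.58 and igfbp1a at 1.12, and the growth factor igf1 at -2.21. Of 10 lists that passed, 2 did so with an estimated correlation. Of called genes 32.9% were higher, against 43.0% with median scaling, 76.5% with spike-in scaling and 25.02% on probes detected everywhere, and the median of all genes was 0.00, between -0.09 and 0.43 under other scalings. Slides held no array of both arms. Normexp left 133 higher and 252 lower, and without 65d male sample 2 and the 1y9m samples 352 were higher and 724 lower.

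**Figure D4:**
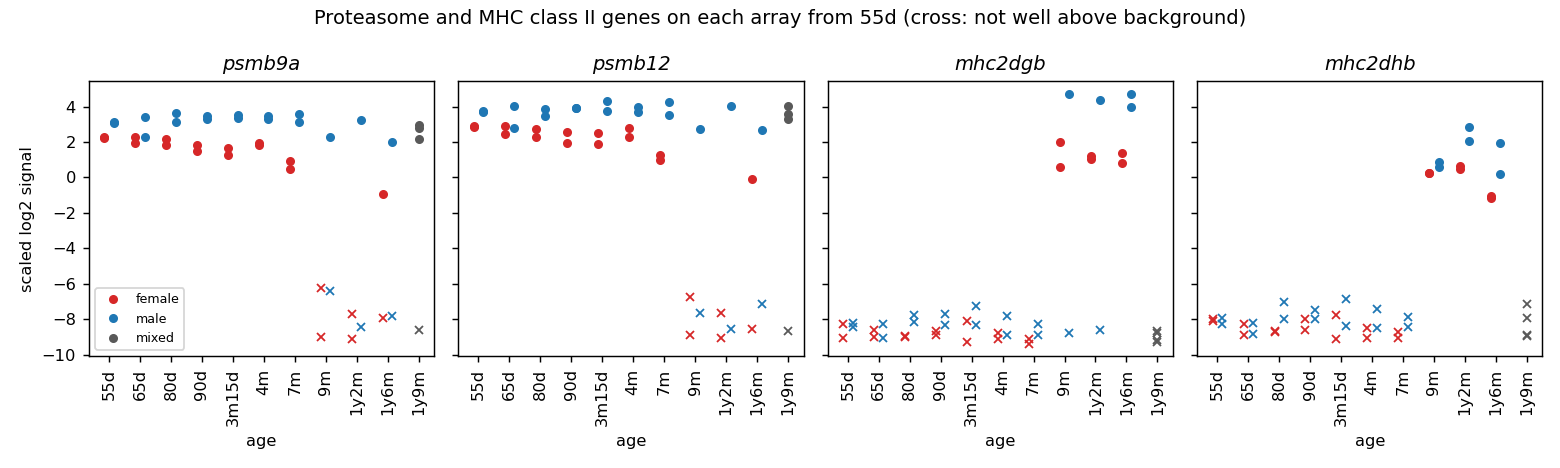
Scaled log2 signal of psmb9a, psmb12, mhc2dgb and mhc2dhb (y) by age from 55d to 1y9m (x), 1 mark per array, a circle where well above background and a cross where not, red for female, blue for male and grey for mixed. In old adults mhc2dhb was read on 8 of 8 arrays and psmb9a on 3, in young adults on 0 and 12, and at 1y9m on 0 and 3 of 4.

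Did ageing differ between the sexes? The old minus young change was more positive in females than in males for 408 genes and more negative for 405 (10 arrays against 10). The most positive were the sulfotransferase hs6st3b at 6.49 (SE 0.54, adjusted p = 3.81e-16), tmem45a at 5.30 (SE 0.89), lgi3 at 4.46 (SE 1.04) and the class I gene mhc1zca at 4.13 (SE 0.77). The sperm gene ropn1l followed at 3.81 (SE 0.46) and gfus.3 at 3.64 (SE 1.26, adjusted p = 0.0366). In the other direction stood znf1156 (-5.66, SE 1.01), her8a (-5.11, SE 0.50), prmt8b (-4.52, SE 0.58), kcnn1b (-4.49, SE 0.53), gtf2h1 (-4.27, SE 1.22) and dck (-4.18, SE 0.32). Replication and mitosis genes were the only list to pass, at 0.0498 with 0 members called by limma and a median 0.34 below all genes (adjusted p = 0.997 with an estimated correlation). Testis genes had 3 more positive, or 2 adjusted over the list alone, and red cell genes 2 more positive and 2 more negative, or 2 and 4. Ovary genes had 3 more negative, or 1 adjusted over the list alone, and ageing and damage genes 3, or 4. The split was 50.2% more positive, against 65.0% with median scaling and 71.2% with spike-in scaling. Normexp left 12 more positive and 16 more negative, spike-in scaling 146 and 59, and group means as units 109 and 86.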

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

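The tests of the egg to zygote step, of the proteasome genes in old fish and of the segmentation steps were chosen only after those results were seen; the 10 regroupings of all samples were fixed before, the one without 65d male sample 2 was not. The test of old fish first took all 12 named genes, of which mhc2dhb, rangap1b, ugt2a2 and crygmxl2 showed no adult pair more than 16-fold apart, and was then narrowed to psmb9a, psmb12 and psmb13a.

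Samples apart within a group were looked for with Dixon's ratio in the only group of 4 samples, 1y9m, over the means of 25 lists. By chance about 1 list in 20 would exceed its critical value. The lists over the critical value were skeletal muscle (0.9816), heart (0.8430), lens (0.9607), retina (0.9255), skeleton and matrix (0.9430), yolk and estrogen (0.9358), replication and mitosis (0.8941), pigment (0.9289) and stress (0.8521). For yolk and estrogen genes sample 3 stood apart (3.32 against -2.69 to -2.30). For muscle genes sample 4 did (2.81 against 1.65 to 1.67). Samples 1 and 2 of that age were the most alike pair of all, with a correlation of 0.997 and an SD of differences of 0.261, where the next pair had 0.352. The labels call all of them mixed in sex, whereas the design text counts 11 adult stages with males and females each, so their sex is unclear.

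The difference between the sexes varied with age for 819 genes upwards and 1323 downwards, and ageing varied with sex for 408 and 405; they are listed here because an effect differed between groups. The first pair of counts had a real grouping of 2142 called genes against 1938 in the highest other of 100 regroupings (value 1). Without 65d male sample 2 the real grouping had 1271 against 875 in the highest other of 50. The real grouping ranked first, but another grouping of the same ages came close with all samples, so chance was not excluded. The second had 10 regroupings, real 813 and highest other 448, which is too few. Of the 22180 probes without a gene name 65.78% were called between females and males, against 62.9% of named genes; they are listed because they were left out of the results.

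Egg to zygote had 5169 called genes in a step of minutes, before the embryo transcribes its genome. Genes near background are no full account, because 51.06% of the 7093 genes well above background on all 4 arrays passed. The egg arrays were dim as a whole, with a 75th percentile of 125 and 186 against 508 and 545 in zygotes. That filter cannot exclude an effect of such dimness on brighter genes. The 2 time points shared 0 slides. In cleavage against egg, slide as a fixed block left 1979 genes higher and 3801 lower, near the 1994 and 3991 without it. That fit joined the slides of egg and cleavage only through a single cleavage array of 1h45min, beside adult arrays. The zygote step was not fitted so, and slide cannot be told apart there. Scaling is no full account, because the lowest count over the other 4 scalings was 3029. Another family of fish stays open for part: of 232 genes over 16-fold apart, 9.05% were also all-or-none in some pair of adult replicates, against 1.53% of the others, a ratio of 5.93 (Fisher's exact p = 3.27e-10). Activation of the egg, with lengthening of poly(A) tails, was not tested.

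Between young and old adults psmb9a, psmb12 and psmb13a fell together, though at 1y9m they were read on 3 of 4 arrays. Another family of fish stays open, since in 4 of 14 adult pairs, all at 9m or older, all 3 genes differed more than 16-fold between replicates of one age and sex, and in no pair of the young adults. Fewer leukocytes argue poorly for it: 23 genes of the leukocyte list, left after taking out its antigen presentation genes (names in psmb, mhc, tap, b2m and cd74), had a median change of 0.6879 (quartiles 0.172 and 1.53). Slide argues poorly for it too, since on 5 of 13 slides with several adult arrays of one sex the 3 genes differed that much. Of 69 genes at least 8-fold apart, 17 had another within 5 positions along its chromosome, where random draws had a median of 4 and at most 21 (permutation p = 3.00e-04), so linked variants stay open; neighbouring copies may also share probes.

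Fewer genes were called per step in segmentation and pharyngula than in gastrula. Slide changes argue poorly for it, as among steps whose time points shared 2 slides the gastrula median was 56.4 times the median of the later periods. Median intervals were not shorter in the later periods, at 1 hour in gastrula, 1 hour in segmentation and 3.5 hours in pharyngula. Dividing by hours could therefore not close the gap. Per hour the ratio of segmentation to gastrula was 0.0156, with 1027 genes per hour in gastrula, 16 in segmentation and 3.13 in pharyngula. With normexp, which damps signals near background, the medians were 2.5 in gastrula, 0 in segmentation and 0 in pharyngula. Signals near background may thus carry much of the difference, which was not tested. A slower pace of change stays open, as does a mix of tissues that dilutes local change.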

How the results depend on the processing

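The tests with slide as a fixed block, with probes detected on all arrays, and without the 65d and 1y9m samples were chosen only after the results were seen. The signal over background limits every fold: processed signals near the floor turn small differences into large log2 values, and normexp with an offset of 50, which damps them, lowered most counts. Most groups had 2 arrays. Blank scan dates kept a scan-day block from being run; the mean spot signal was absent, so normexp used medians. The cause of the changes below was not tested.

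Normexp gave, higher and lower: cleavage against egg 923 and 2043, segmentation 1143 and 1091, pharyngula 808 and 494, hatching 406 and 191, larva 901 and 657, adult higher 1391, sexes by age 194 and 15, old against young 133 and 252, ageing by sex 12 and 16. Step medians were zygote 1514, cleavage 0, blastula 21, gastrula 2.5, segmentation 0, pharyngula 0, hatching 1, larva 38 and juvenile 13. List medians turned in segmentation for retina (-0.1273, from 0.467) and pancreas and gut (-0.1714, from 0.579), and in sexes by age for ribosomal (0.1263, from -0.288) and respiratory chain (0.291, from -0.238).

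Spike-in scaling gave cleavage 3999 and 520, segmentation 3685 and 984, pharyngula lower 416, hatching lower 142, larva lower 760, adult higher 3760, female against male 5605 and 614, sexes by age 2499 and 126, old against young 1023 and 314, ageing by sex 146 and 59; step medians were zygote 3029, cleavage 1, blastula 126, gastrula 200, segmentation 3, pharyngula 0, hatching 34, larva 72 and juvenile 68. Median scaling gave gastrula 1615 and 5209, pharyngula lower 1740, hatching lower 710, sexes by age 2249 and 331. Quantile normalization gave cleavage lower 1792 and a cleavage step median of 61. The 75th percentile over probes detected on all arrays gave cleavage lower 1844, segmentation lower 1422, pharyngula lower 486, hatching lower 174, larva lower 758, female higher 1878, sexes by age 267 and 2699. By construction each of these but quantile normalization moves all genes of an array together; quantile normalization moves a gene by its rank.

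The adjusted p alone gave gastrula higher 4285, segmentation 3888 and 4963, pharyngula 3178 and 4810, hatching 2002 and 3164, larva 2616 and 4141, adult 4938 and 4047, female higher 4479, sexes by age 3375 and 2608, old against young 2295 and 2308, ageing by sex 762 and 793. At least 1.5-fold gave segmentation lower 3667, pharyngula lower 2725, hatching 1502 and 1522, larva lower 2685, adult higher 3409, sexes by age 2397 and 2357, old against young 934 and 1512, ageing by sex 696 and 695. Looser thresholds call more by construction.

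Slide as a fixed block gave pharyngula 868 and 357, hatching 484 and 195. With it cleavage (1979 and 3801) and larva (1242 and 1142) stayed within 1.5 times. Slide as a random block moved step medians to cleavage 43, segmentation 31, pharyngula 21.5 and hatching 203. Replicate number as a block moved them to cleavage 31, segmentation 26 and pharyngula 15; numbers were not taken to pair samples, as the correlation of deviations had a median of 0.0845 over 2211 pairs of time points (from -0.434 to 0.696). It was over 0.1 in 42.2% of pairs, with a median of 0.278 on one slide and 0.0814 on other slides, so some pairing by slide remains. Group means as units gave ageing by sex 109 and 86. The filter asking for detection on 0.5 of the arrays turned the hatching gland median in larvae to 0.177, from -0.034, and leaving out hatching 2d replicate 2 turned it to 0.003018, where the lowest, without hatching 2d replicate 1, was -0.06368.

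Of the gene counts, leaving out single arrays moved only sexes by age by more than 1.5 times: higher 494 without 65d male replicate 2 and 1300 without replicate 1, lower 777 without replicate 2 (highest 1809, within 1.5 times). Such fits also reversed 1 list median, strengthened 34 and weakened 46, and weakened 20 values of named genes. Without 65d male sample 2 and the 1y9m samples it was 530 and 816. Lists past the threshold with an estimated correlation were cleavage 0 of 2, gastrula 2 of 11, segmentation 5 of 17, pharyngula 7 of 16, hatching 2 of 9, larva 6 of 14, adult 5 of 19, female against male 0 of 18, sexes by age 0 of 16, old against young 2 of 10 and ageing by sex 0 of 1 in camera; fry gave 21 for cleavage, 24 for gastrula and 0 for ageing by sex. Of 132 named genes 22 weakened with normexp, 6 with group means, 3 each with the random block and spike-ins, and 1 with array weights; with the fixed block 3 weakened and 45 did not. The 22 gene counts stayed within 1.5 times with array weights, the deposited table, the mean of all probes, no filter, the random block and the replicate block. The deposited table held the same values, so that result was fixed in advance. In groups of 2 arrays both had the same weight, so weights could not favour either replicate.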

Other observations

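The tests named here were chosen only after the results were seen, apart from the regroupings that were not drawn within each sex.

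Means of the germ cell lists were higher in the last larval samples than at 24d, before the sexes were sampled apart. The values in this paragraph are list means, and no list test was run between these time points. The mean of the ovary list was -2.53 and -2.76 at 24d, 1.18 and 0.90 at 30d, 3.41 and 2.74 at 40d and 3.12 and 3.49 at 45d. Oocyte and germ plasm genes went from -2.78 and -2.90 at 24d to 2.93 and 3.39 at 45d, while the testis list stood at -3.11 and -3.16 and later at -1.87 and -1.93. Sexed females from 55d on had an ovary mean of 4.00 to 4.69, males other than 65d sample 2 one of -4.49 to -1.42. Yolk and estrogen genes followed later, at -1.69 and -1.85 at 45d and 2.77 and 2.06 in females of 55d.

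Single blood and eye genes moved apart, without a test of a switch. In adults against larvae the globin hbaa2 rose by 4.82 while hbbe2 fell by 7.80, and the green cone opsins opn1mw4 (5.24) and opn1mw1 (-7.93) had opposite signs, while the red cell list did not pass and most retinal genes fell. The mean of the leukocyte list was -3.06 and -3.14 at 4d and 0.44 and 0.47 at 40d, without a test of the course between. The mean of the pancreas and gut list was 2.01 and 2.02 at 4d and 3.725 and 3.598 at 6d, also without a list test of that step.

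Of the 1y9m samples, samples 1 and 2 had ovary means of -1.30 and -1.34 with testis means of 1.98 and 1.94, outside the ranges of both sexes for testis genes (highest male 1.22). Sample 3 had an ovary mean of 4.04 and sample 4 of -4.04. On the scale from male to female they lay at 0.348, 0.334, 0.887 and -0.03. These values have no explanation here.

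One sample labelled as a 65d male lay at 0.775 on that scale and correlated at 0.969 with the 45d juveniles, where the other 65d male had 0.925. One hypothesis is that a late male still carried the oocytes that zebrafish pass through; another is that one of the 2 pooled fish was a female. Without that sample and the 1y9m samples, sexes by age had 530 genes higher in place of 819, which either could produce. Genotyping or histology of fish of that age would separate them.

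A hypothesis for the step from egg to zygote is that squeezed eggs and laid eggs came from other mothers, as the ratio of 5.93 may reflect. RNA of eggs and zygotes from the same clutch would test it, with total RNA beside poly(A) RNA. For psmb9a, psmb12 and psmb13a the hypothesis is that haplotypes of the region are carried or not by a family, as the 4 adult pairs apart could mean. Genotyping single fish of both ages would test it.

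Regrouping of the arrays at random gave the highest other count and the real one as follows. In segmentation 0 against 4401, pharyngula 141 against 2641, hatching 0 against 1376 and larva 193 against 2510, called by limma, the real grouping ranked first. The same held for gastrula, with 4177 against 5789, adult, with 2684 against 4171, and female against male, with 2045 against 6486. Single arrays were regrouped, although replicates and neighbouring time points resemble each other and arrays shared slides. These ranks therefore cannot tell stage or sex from slide or family of fish. No slide held both arms in gastrula, adult or female against male. Old against young had 374 in the fit of 2 groups without sex, and 2 of 100 groupings reached it, the highest with 4619. That fit says little, because both arms held females and males. Drawn within each sex, in a fit with sex, the real grouping ranked first, with 1021 against 213 in the highest other of 100. Single arrays were drawn here too, although replicates of the same age resemble each other, and no slide held both arms. This rank therefore cannot tell age from slide or family of fish either.

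How old the genes of each stage are in evolution was not analysed here, since ages of genes were not used here. A test of the pharyngula by gene age would need them. Of unnamed probes 51.3% were called in cleavage against egg (57.6% of named genes), 54.3% in gastrula (56.2%), 36.7% in segmentation (42.8%), 22.7% in pharyngula (26.02%), 11.2% in hatching (13.3%), 21.1% in larva (25.95%), 46.4% in adult (41.0%), 23.2% in sexes by age (20.6%), 13.7% in old against young (10.3%) and 6.73% in ageing by sex (7.83%). In some comparisons their balance of higher and lower differed from that of named genes. In cleavage 2297 were higher and 9082 lower (named genes 1994 and 3991), and in female against male 3747 and 10844 (2905 and 3631). In sexes by age it was 1145 and 4004 (819 and 1323). These leaned lower in both sets. In gastrula it was 7644 and 4397 (2847 and 2990) and in adult 3542 and 6746 (2119 and 2136). In others the balance was close, as in segmentation, 4151 and 3981 (2196 and 2247).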
